A study of Brassica rapa subsp. pekinensis with 6 samples.

How the data were processed

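RNA from fully expanded petals of 3 doubled haploid and 3 autotetraploid samples of Chinese cabbage was extracted with TRIzol, and 3 µg per sample went into libraries made with a NEBNext Ultra RNA kit. The submitters' processing notes list Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0 without stating the step of each. The genome build and annotation are not given in the sources used here.

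The authors' deposited table holds 1 row per called gene, 14412 in all. For each it gives a signal that the authors computed for each group, a normalised read count combined over its 3 libraries, the log2 ratio of the autotetraploid to the doubled haploid value as the authors' deposited log2 fold change, the authors' p-value and their adjusted p-value. The name of the file speaks of FPKM, but its headers call the values read counts. Their log2 ratio equals the deposited log2 fold change to within 4.999e-05. All genes have an adjusted p below 0.05, so unchanged genes were not analysed here. The ratio of adjusted p to p and rank points to 35362 genes tested by the authors, of which 40.8% are in the table. Group totals over all genes and total reads per library are not given in the sources used here, so sequencing depth is not known.

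The group values were found to be means of whole reads divided by a factor for each library. With these factors, 99.96% of the 7827 autotetraploid values up to 400 and 99.99% of the 7749 doubled haploid values matched a single set of 3 read numbers within 0.55 of the last written decimal. Random decimals matched a set in 2% of autotetraploid and 2.5% of doubled haploid values just above 100, and in 9.5% and 26% between 300 and 400. This gave read numbers in all 6 libraries for 6930 genes, or 48.1%. The recovered libraries carry no replicate number, so they cannot be tied to the labelled replicates. On simulated data, 97.4% of values gave a single set, and 100% of these were the simulated reads. Larger values stay as group values with no SD.

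The plan written before the data were examined was a limma test on values per library for all genes, with camera for gene lists and chromosomes. With called genes and group values only, these tests, counts adjusted over the list alone and values with an estimated correlation could not be computed over all genes. On the 6930 genes with recovered reads, limma alone was run. Terms of a gene ontology were not tested. In place of the planned tests, the direction of change was tested. For each of 34 gene lists and 10 chromosomes, the share of called genes higher in the autotetraploids was compared with that of the other called genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists or chromosomes and a threshold of 0.05. This test treats genes as independent, which members of a list are not, and its p-values measure only the spread among genes of these libraries. It asks about direction among called genes, not whether a list changed more often than others. Lists with at least 5 called genes were tested. In data simulated with the observed trend over expression level and no list effect, 0.24 lists passed per draw, and 0.04 when tested within bins. The direction of each gene was drawn independently there, so these rates do not cover genes of a list that move together.

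Genes were assigned to lists by the protein names that the table pairs with them, since 0 of its identifiers occur among the 51589 entries of the reference. Matches to other proteins that share a symbol were removed, a step that was not in the plan. The rule for named genes took the 8 largest increases and the 8 largest decreases with a description whose libraries do not overlap, the 3 members of each list with the smallest p, and the most abundant member of 3 lists for other tissues. Genes listed at 0 in a group have no finite fold change and were left out of the ranking by size, a choice made after the data were seen. Where read numbers could not be recovered the overlap was not checked. Genes that tied for the smallest value were ordered by mean. Genes outside the rule are named as chosen after their values were seen. A fold against 1 to 3 reads is given with an exact Clopper-Pearson interval at 95%, computed from the reads and the factors of the libraries.

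On the recovered libraries, limma 3.58.1 was run in R 4.3.3 on log2 values with a pseudocount of 0.5, eBayes with a trend, and adjustment over 35362 genes. In libraries simulated for 6930 genes, a part of those with a mean of at least 30 was changed. It recovered 100% of genes changed 2-fold and passed 4 unchanged genes, with adjustment over the 6930 genes only. The shift of a chromosome was estimated from the tails of its fold changes between 0.6 and 2.0 on the log2 scale, with 300 bootstrap resamples of genes. A simulated shift of 0 gave 0.0077, and a simulated loss of 1 of 4 copies gave -0.39. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

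Alternatives were a change of at least 2-fold, an adjusted p under 0.01, a mean group value of at least 100, group values scaled to equal sums, tests within 20 bins of the mean value, lists without exclusions, the auxin list without SAUR genes, and removal of chromosome A01 or of ribosomal protein genes. For limma they were a pseudocount of 0.1, other settings of eBayes and leaving out each library, which was also done for the folds of named genes. Only the fold-change threshold for the number of called genes was planned. Lists without exclusions follow the list rule as planned, and the other alternatives were chosen after the data were seen.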

Results

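Gene expression was measured by RNA sequencing in fully expanded petals of Chinese cabbage (Brassica rapa subsp. pekinensis) at the flowering stage. The 2 groups were doubled haploid plants, which carry a doubled single chromosome set, and autotetraploid plants, which carry that set doubled again. Both were generated from the doubled haploid line 'FT' and grown under the same conditions, with 3 biological replicates in each group and 6 libraries in all. The authors' deposited table gives, for 14412 genes below an adjusted p of 0.05, the normalised read count of each group combined over its 3 libraries, so most values below are the authors' group values and have no spread of their own. Total reads per library are not given in the sources used here. Reads were divided by a normalisation factor for each library, which was read from the steps of the group values. These factors were 0.988, 0.840 and 0.779 for the autotetraploid libraries and 1.23, 1.17 and 1.11 for the doubled haploid libraries. They need not equal relative sequencing depth. Genes are named by the protein that the table pairs with each identifier, and the chromosome is the one in the identifier. Start and end positions and the genome build are not given in the sources used here.

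The comparison asked which genes differ in petals between autotetraploid and doubled haploid plants of the same line. Of the 14412 called genes, 7404 were higher and 7008 lower in the autotetraploids. The heat stress factor gene HSFB2A, the regulator BHLH101 and inositol-3-phosphate synthase were among the 8 largest increases. The clock gene LUX and a sugar transporter gene were among the 8 largest decreases. HSFB2A (BraA02004308) had 60.2 ± 5.3 normalised reads (SD, n = 3) in the autotetraploids and 1.14 ± 0.50 (SD, n = 3) in the doubled haploids. The iron deficiency regulator BHLH101 (BraA03000156) had 79.4 ± 21.2 against 1.43 ± 0.99 (SD, n = 3 each), and a gene described as ORG2-like, a related regulator, had 62.3 ± 16.1 against 1.44 ± 0.55 (SD, n = 3 each). Inositol-3-phosphate synthase (BraA01000082) had the authors' values of 662.8 and 15.4. WSD1 (BraA05000675), a wax ester synthase, had 67.3 ± 2.2 against 2.04 ± 2.28 (SD, n = 3 each). Without the highest doubled haploid library, the doubled haploid value was 0.856 for BHLH101 and 0.811 for WSD1. The doubled haploid values of these genes with an SD rest on few reads over the 3 libraries. There were 4 for HSFB2A, 5 each for BHLH101 and the ORG2-like gene, and 7 for WSD1.

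Among the decreases, LUX (BraA01002149), a component of the evening complex of the clock, had the authors' values of 11.6 in autotetraploids and 491.7 in doubled haploids. The RNA-binding protein gene GRP1A (BraA09001180) had 222.4 against 9492 in the authors' values. JMJD5 (BraA05001415), a putative histone demethylase linked to the clock, had 4.93 ± 5.76 against 254.2 ± 11.9 (SD, n = 3 each), and without its highest library the autotetraploid value was 1.61. A WAT1-related gene (BraA09002863) had 2.23 ± 0.89 against 87.1 ± 2.5 (SD, n = 3 each), and its autotetraploid value rests on 6 reads over the 3 libraries. A 14 kDa proline-rich protein gene (BraA03002483) had the authors' values of 17.7 and 704.1.

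Of these 16 extreme genes, 6 rested on 1 to 3 reads in the lower group. The sugar transporter gene ERD6-like 16 (BraA10000099) had 1 read in the autotetraploids and 803 in the doubled haploids, a decrease of 534.4-fold with a 95% counting interval of 106.7 to 23580. COL10 (BraA02003880) had 3 reads against 327, a decrease of 84.9-fold (27.5 to 394.6). ERF013 (BraA07003788) had 2 against 96, a decrease of 40.7-fold (9.60 to 298.6). In the other direction, HSP17.6 (BraA10000610) had 67 reads in the autotetraploids against 2, an increase of 42.5-fold (12.01 to 380.1). A glutamate-glyoxylate aminotransferase 2 gene had 33 against 1, an increase of 43.6-fold (7.44 to 1808). CYP71B2 (BraA01000689) had 23 against 1, an increase of 31.2-fold (5.03 to 1276). These intervals cover counting error only, and the folds also rested on single libraries. COL10 had 96.0 ± 91.9 normalised reads (SD, n = 3) in the doubled haploids and a fold between 38.0 and 189.6 when 1 library was left out, the lowest without the highest doubled haploid library. The aminotransferase gene had 13.1 ± 10.8 (SD, n = 3) in the autotetraploids and a fold of 23.8 without the highest. HSP17.6 had a fold of 28.4 without the doubled haploid library that had none of its reads. For ERD6-like 16, ERF013, CYP71B2 and the aminotransferase gene, the lower group was at 0 without 1 library. Read numbers could be recovered for 12 of the 16 genes. Left out of this ranking were 26 called genes listed at 0 in the autotetraploids, with up to 307.4 in the doubled haploids, and 10 listed at 0 in the doubled haploids, with up to 19.3 in the autotetraploids.

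The size of the changes was moderate for most genes, with a median change of 1.64-fold. A change of at least 2-fold was seen in 4816 genes, of which 1645 were higher and 3171 lower in the autotetraploids. The direction depended on expression level. Among genes with a mean group value under 30, 27.4% were higher in the autotetraploids, against 81.5% among those over 3000. The group values of the called genes summed to 17241772 in the autotetraploids and 13568052 in the doubled haploids, and scaling the groups to equal sums, a shift of 0.35 on the log2 scale, gave 5768 genes higher and 8644 lower. Genes higher by less than 1.27-fold therefore turn with that scaling.

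**Figure D1:**
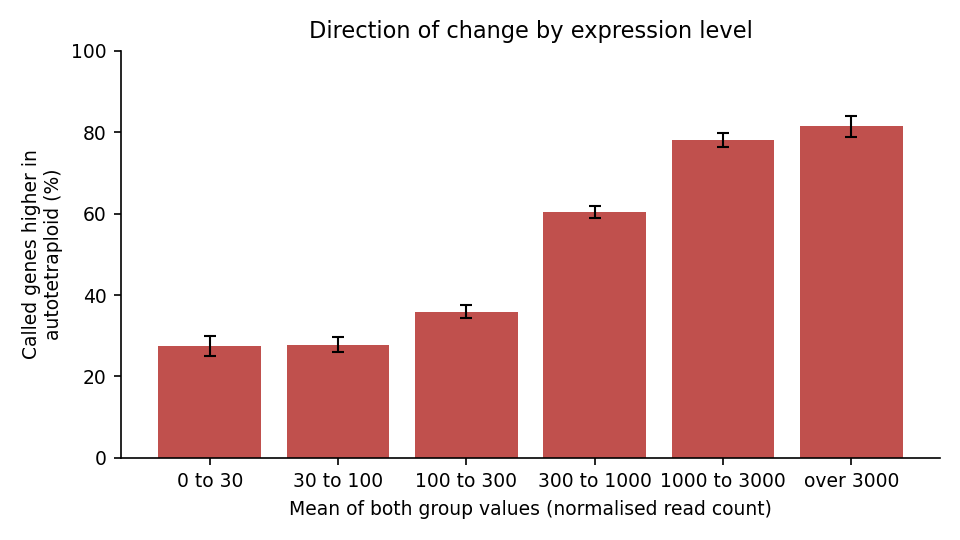
Bars give the share of called genes (%) that were higher in the autotetraploids, in 6 classes of the mean of both group values (normalised reads), with 95% Wilson intervals. The share was 27.4% in the lowest class and 81.5% in the highest.

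Gene lists fixed before the data were examined were tested for direction: the share of a list's called genes that were higher in the autotetraploids was compared with that of the other called genes by Fisher's exact test, two-sided, with adjustment over 34 lists. Of these, 13 passed, 9 with more genes higher and 4 with more genes lower than the rest. Matches to other proteins that share a symbol had been removed, which was not in the plan. With every match kept, as planned, 15 lists passed. The added lists were ethylene and DNA methylation and silencing (Fisher's exact test, adjusted p = 0.0199 each). None of the 13 turned its direction under equal sums, where the floral organ identity and cellulose lists lost their calls.

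**Figure D2:**
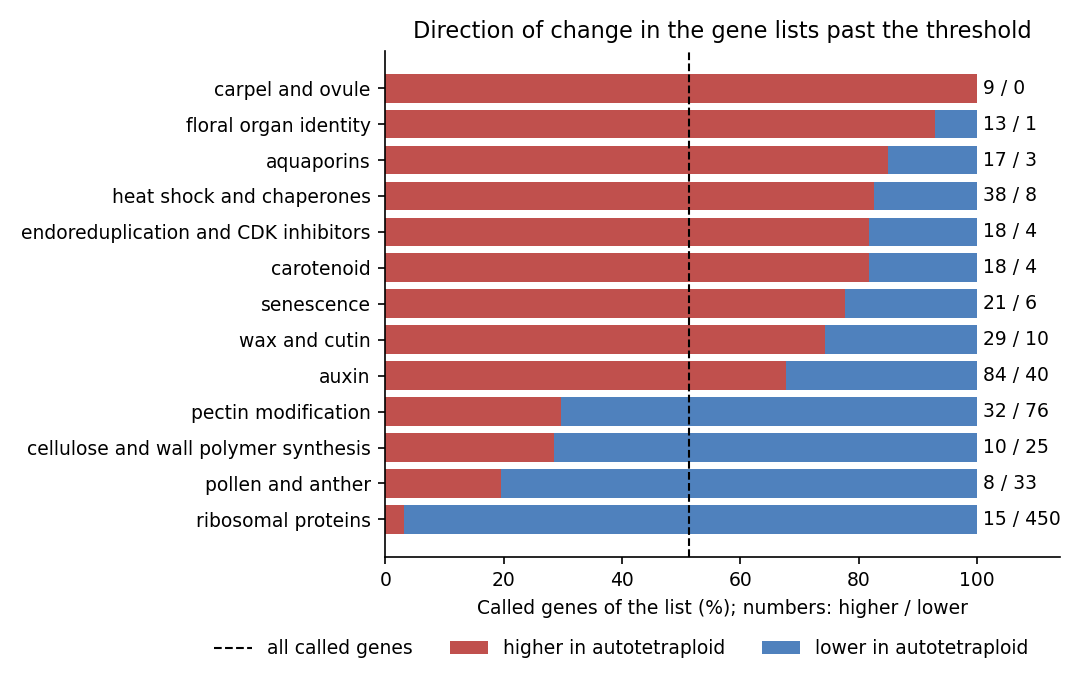
Each bar splits the called genes of a list (%) into those higher and those lower in the autotetraploids, with the counts at the right, for the 13 lists past the threshold. The dashed line marks the 51.4% of all called genes that were higher. Ribosomal proteins had 15 genes higher and 450 lower.

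Genes for ribosomal proteins, the protein components of the translation machinery, were lower in the autotetraploids almost throughout. Of 465 called genes, 450 were lower and 15 higher (Fisher's exact test, adjusted p = 1.34e-119), with a median change of -1.09 on the log2 scale. Among the genes described as 40S or 60S proteins of cytosolic ribosomes, a subgroup chosen after the values were seen, 336 of 340 were lower. Those of plastid ribosomes were lower in 45 of 51 and those of mitochondrial ribosomes in 27 of 29. RPL14B (BraA03005706) had the authors' values of 537 in autotetraploids and 1549 in doubled haploids, RPL26A (BraA09003897) had 420.4 and 1320, and RPS2C (BraA05004217) had 1069 and 2580. The authors' deposited table lists an adjusted p of 7.8e-110 for RPL14B.

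Heat shock and chaperone genes were higher in 38 of 46 called genes (Fisher's exact test, adjusted p = 0.000216), with a median change of 0.998 on the log2 scale. The small heat shock protein gene HSP17.6B (BraA05000646) had the authors' values of 1683 in autotetraploids and 201.0 in doubled haploids, and a second HSP17.6 gene (BraA10000611) had 1935 and 368.6. HSFA2 (BraA03002709), a transcription factor of the heat response, had 767.9 and 98.7, and the chaperone gene HSP90-4 (BraA02000946) had 4374 and 1532. Both were chosen after their values were seen. A gene described as small heat shock protein C4 (BraA10002673) went the other way, with 1659 against 7309.

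Auxin genes were higher in 84 of 124 called genes (Fisher's exact test, adjusted p = 0.00187). IAA14 (BraA08002634), a repressor of auxin signalling, had the authors' values of 9491 in autotetraploids and 3058 in doubled haploids. TAA1 (BraA02002169), an enzyme of auxin synthesis, had 5594 and 2433. SAUR genes, a family of early auxin-responsive genes, supplied 50 of the 124 and were higher in 39, and without them the list had 45 genes higher and 29 lower and lost its call (adjusted p = 0.186, and from 1.12e-06 to 0.186 over 9 alternatives). SAUR15 (BraA04000770) was among the 11 lower SAUR genes, with 20.4 against 675.5.

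Genes that specify floral organs were higher in 13 of 14 called genes (Fisher's exact test, adjusted p = 0.0109), although this call was lost in 3 of 7 alternatives (adjusted p from 0.0128 to 0.12), among them the test within bins of expression level. PISTILLATA, a petal and stamen identity gene, had the authors' values of 49047 and 18726 at one copy (BraSca000919) and 15439 and 10434 at another (BraA02001415). SEP1 (BraA10000355), its partner in floral organ identity, had 5724 and 3181. In the carpel and ovule list, 9 of 9 called genes were higher (adjusted p = 0.0157). The members were NGATHA genes, which act in style and lateral organ growth, and BEL1, an ovule regulator, with 713.8 and 468.1 for NGA1 (BraA05004374) and 2030 and 1248 for BEL1 (BraA04001438). The list lost its call in 1 of 7 alternatives, among genes with a mean of at least 100.

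Genes that restrain the mitotic cell cycle or act in endoreduplication, the doubling of DNA without division, were higher in 18 of 22 called genes (Fisher's exact test, adjusted p = 0.0157). The inhibitor gene SMR1 had the authors' values of 12022 and 7905 at one copy (BraA05002830) and 2650 and 1559 at another (BraA01004292), and SMR3 (BraA03000079) had 1426 and 703.3. The call was lost in 4 of 8 alternatives, among them the restriction to changes of at least 2-fold. Core cell cycle genes did not pass, with 6 called genes higher and 10 lower. Petal and organ size regulators had 9 higher and 15 lower (adjusted p = 0.357).

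Aquaporins, which are membrane water channels, were higher in 17 of 20 called genes (Fisher's exact test, adjusted p = 0.0133), a call lost in 2 of 8 alternatives (adjusted p from 0.0026 to 0.161), among them the test within bins of expression level. PIP2-1 had the authors' values of 30195 and 5323, and TIP1-1 (BraA04002773) had 1869 and 466.1. Wax and cutin genes, which build the petal surface, were higher in 29 of 39 (adjusted p = 0.0175). WSD1 (BraA01003636) had 4681 and 1118, the transporter gene ABCG12 (BraA05000821) had 6245 and 2747, and 3-ketoacyl-CoA synthase 6 had 7498 and 3393. That call was lost in 2 of 8 alternatives, without the genes of chromosome A01 and at a mean of at least 100 (adjusted p from 2.55e-05 to 0.269 over the 8).

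Carotenoid genes, which make the yellow pigments of the petals, were higher in 18 of 22 called genes (Fisher's exact test, adjusted p = 0.0157). ZEP (BraA07001678) had the authors' values of 19313 and 8349, PDS (BraA08002692) had 7718 and 4100, and CCD1 (BraA04000711), which cleaves carotenoids, had 16973 and 8064. That call was lost in 3 of 8 alternatives (adjusted p from 0.00197 to 0.12), among them the test within bins of expression level. Senescence genes were higher in 21 of 27 (adjusted p = 0.0181), a call lost in 4 of 8 alternatives (adjusted p from 0.0143 to 0.39), again with the test within bins among them. The chlorophyll breakdown genes SGR1 (BraA03005404) and PPH (BraA03000622) were higher, with 4579 against 1993 and 4319 against 2041. SAG12 (BraA06000198), a senescence-specific protease gene, was lower, with 683 against 2015.

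Pectin-modifying genes, which alter the cell wall, were lower in 76 of 108 called genes (Fisher's exact test, adjusted p = 0.000109), with a median change of -1.002 on the log2 scale. A putative pectate lyase gene (BraA05002914) had the authors' values of 179.3 and 1063, and PME3 (BraA01004052) had 463.3 and 2388. PGIP1 (BraA01004238), a polygalacturonase inhibitor, was higher, with 859.7 against 126.0. Pollen and anther genes moved with this list. They were lower in 33 of 41 called genes (adjusted p = 0.000448), with a median change of -1.06 on the log2 scale. PPME1 (BraA10000977), a pollen pectinesterase chosen after its values were seen, had 665.2 and 1601. The 3 members of the pollen and anther list with the smallest p were higher and were copies of TKPR1, a sporopollenin enzyme, of which BraA06002382 had 6521 and 2673. The pollen and anther call was lost among changes of at least 2-fold.

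Genes for cellulose and other wall polymers were lower in 25 of 35 called genes (Fisher's exact test, adjusted p = 0.0263). The cellulose synthase genes CESA2 (BraA01000042) and CESA1 (BraA01000611) had the authors' values of 59.7 and 663.6, and 1982 and 4064. CSLB3 (BraA04002340) was higher, with 18074 against 9930. The call was lost in 4 of 8 alternatives, among them the removal of chromosome A01. Expansin and XTH genes, which loosen the wall, did not pass, with 11 higher and 22 lower (adjusted p = 0.0958). The expansin gene EXPA1 was nonetheless higher at BraA07003532, with 7052 against 2122, and at BraA02002099, with 3064 against 1379.

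The other 21 lists did not pass, so their members are given mostly as counts. Among hormone lists, abscisic acid had 23 genes higher and 16 lower, ethylene 18 and 6, gibberellin 8 and 11 and brassinosteroid 10 and 10. Jasmonate had 17 and 11, which became 14 and 14 under equal sums, and cytokinin had 18 and 14, which became 16 and 16. Flavonoid and anthocyanin genes had 20 higher and 16 lower, and 15 and 21 under equal sums. Glucosinolate genes had 11 higher and 13 lower, and terpene and scent genes 13 and 3. Photosynthesis genes, a marker of green tissue, had 35 higher and 25 lower, and 27 and 33 under equal sums. Their most abundant member, a small subunit of ribulose bisphosphate carboxylase, had the authors' values of 25276 and 23699, a difference that turns under equal sums. DNA repair genes had 6 higher and 16 lower, and DNA methylation and silencing genes 11 and 22. DNA replication and histone genes had 11 and 22 as well, and 5 and 28 under equal sums, where the list passed, as it did at the authors' adjusted p under 0.01 (adjusted p from 0.014 to 0.194 over 8 alternatives). In all, 7 of the 21 lists passed in at least 1 alternative, the others being ethylene, abscisic acid, photosynthesis, DNA methylation and silencing, DNA repair, and terpene and scent. Sugar transport and sucrose cleavage genes had 37 and 28, and 32 and 33 under equal sums. Cold and dehydration genes had 19 and 11, salicylate and pathogen response genes 14 and 18, and genes of the early wound and touch response 18 and 15.

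The circadian clock list had 21 genes higher and 16 lower and did not pass (Fisher's exact test, adjusted p = 0.705). But most of its members split by the time of day at which they peak in Arabidopsis, a division made after the values were seen. Members assigned to neither day onset nor evening are left out of this split. All 13 called copies of day-onset genes were higher in the autotetraploids, 12 of them under equal sums, where APRR7 turned. Of 19 copies of evening genes, 15 were lower and 4 higher, with 3 higher under equal sums, where a copy of LUX (BraA03003700) turned. CCA1 (BraA05004372) had the authors' values of 929.2 in autotetraploids and 210.4 in doubled haploids. LHY (BraA08003463) had 127.7 ± 28.6 against 5.48 ± 3.27 (SD, n = 3 each). CCA1 and LHY were chosen after their values were seen. ELF4, which acts at dusk, had 199.6 and 5847 at BraA04002563 and 131.3 and 3932 at BraA05003800, and APRR5 (BraA06003131) had 449 and 3396. The 4 evening genes that were higher were 2 copies of LUX, a copy of ELF3 and BOA.

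**Figure D3:**
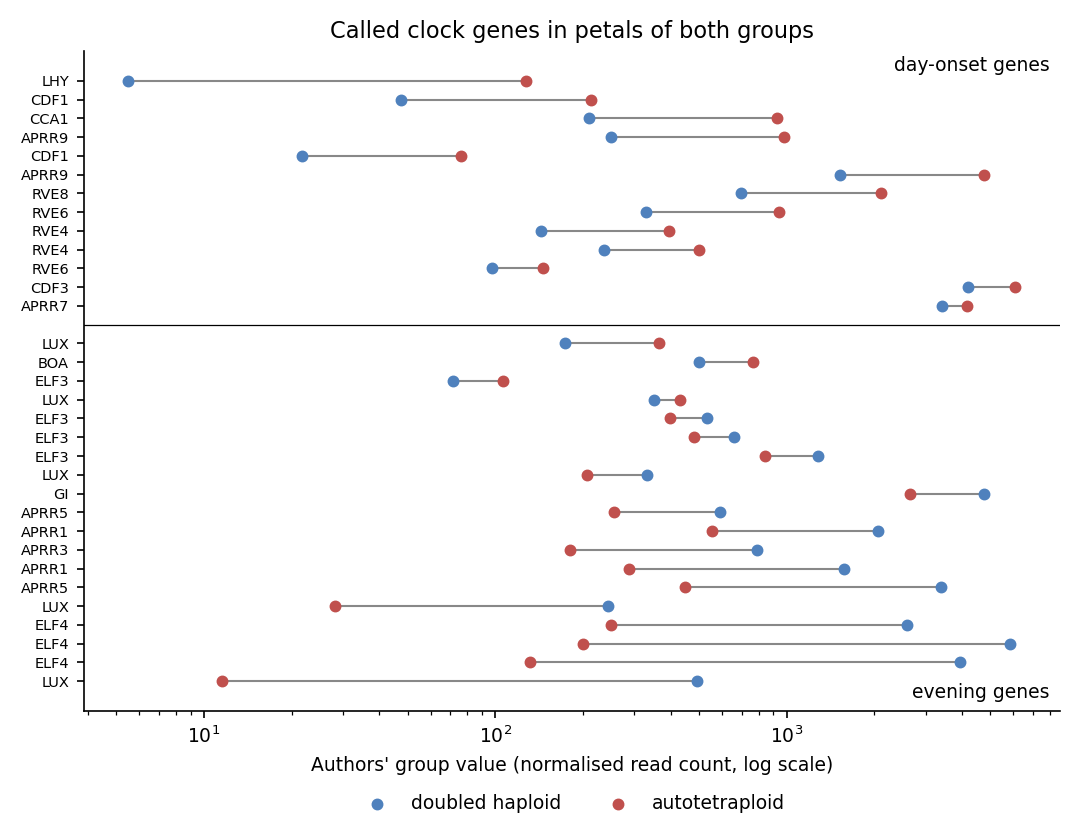
Each line joins the authors' values of a called clock gene in doubled haploids and autotetraploids (normalised reads, log axis), with day-onset genes above and evening genes below. Clock genes assigned to neither are not shown. All 13 day-onset copies were higher in the autotetraploids and 15 of 19 evening copies were lower. APRR7 and the LUX copy with 429 against 351 turn under equal sums.

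Chromosomes were compared to ask whether any differed as a whole between the ploidy groups. Genes of chromosome A01 were higher in the autotetraploids in 528 of 1367 cases, or 38.6%, against 47.7% to 55.2% on the other 9 chromosomes (Fisher's exact test, adjusted p = 4.91e-22). In 10 blocks of 500 gene numbers along A01 the share lay between 30.1% and 50%. The A01 difference was kept in 6 of 6 alternatives (adjusted p from 8.55e-23 to 9.03e-06). Chromosome A03 also passed, with 53.95% against 50.8% on the rest (Fisher's exact test, adjusted p = 0.0306). So did A08, with 55.2% against 50.9% (adjusted p = 0.0283). In both cases the rest includes A01, which lowers its share, and neither was tested without A01. These calls may therefore come from A01 alone. A03 lost its call in 4 of 6 alternatives (adjusted p from 0.0134 to 0.374) and A08 in 3 of 6 (0.00643 to 0.535), both of them at a change of at least 2-fold and under equal sums, and A08 also within bins of expression level.

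**Figure D4:**
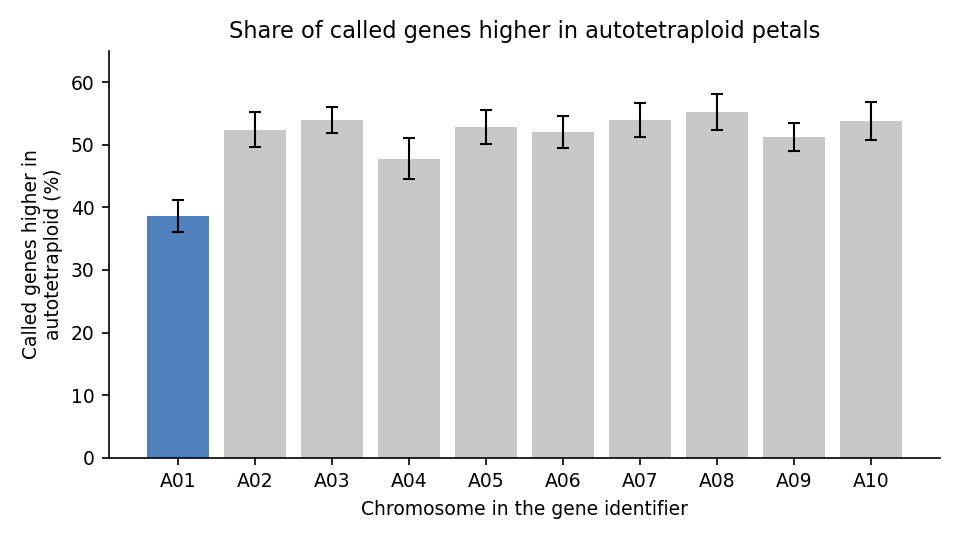
Bars give the share of called genes (%) that were higher in the autotetraploids for each chromosome, with 95% Wilson intervals. Chromosome A01 stands at 38.6% and the other 9 between 47.7% and 55.2%.

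Read numbers in all 6 libraries could be recovered for 6930 of the called genes, those with lower group values. Correlations between libraries were taken across the 5556 of these genes with a mean of at least 30, which are not independent replicates. They were 0.964 to 0.973 within groups and 0.523 to 0.537 between groups. All these genes were called as differing, which lowers the correlation between groups, so the values do not describe all petal genes. The median SD of a gene between libraries of a group was 0.15 on the log2 scale in the autotetraploids and 0.12 in the doubled haploids, for 5556 genes with a mean of at least 30. Counting alone (simulated Poisson reads) gave a median SD of 0.125 in the autotetraploids and 0.093 in the doubled haploids. A limma fit on these libraries passed 6909 of the 6930 genes, 2259 higher and 4650 lower, each in the direction of the deposited table. Because these genes were already called from the same libraries, that count is no independent test.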

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

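Apart from the 2-fold threshold for the number of called genes and the list rule without exclusions, the alternatives here were chosen after the data were seen. The 2-fold threshold left 4816 of 14412 genes. The share of called genes higher in the autotetraploids was 51.4%. It reversed to 34.2% at a change of at least 2-fold and to 40.02% with group values scaled to equal sums, and it moved to 52.3% at an adjusted p under 0.01 and 59.1% at a mean of at least 100. Scaling to equal sums lowers every ratio by construction. A mean of at least 100 leaves out genes of which 27.4% were higher below a mean of 30 and 27.8% from 30 to 100. These genes also had the largest changes, with medians of 1.84 and 1.07 (absolute log2), so more of them enter at 2-fold. The cause of the trend with level, and of the change at an adjusted p under 0.01, was not tested. Of 34 gene lists, 13 passed, against 15 without exclusions, the list rule as fixed beforehand. Where fewer genes were tested, 6 passed at a mean of at least 100 and 8 without chromosome A01. Ribosomal proteins, pectin modification, heat shock and auxin kept their calls in the 8 alternatives of the list tests, and the other 9 lost theirs in at least 1. Auxin lost its call without SAUR genes, an alternative run for that list alone. With a change of at least 2-fold, floral organ identity, brassinosteroid and carpel and ovule had fewer than 5 genes and were not tested, which leaves 7 alternatives for them. Over all lists and these alternatives, 235 of 269 values kept their side of the threshold, 24 lost a call and 10 gained one. Of 3 chromosomes that passed, 1 did so at a change of at least 2-fold and 1 under equal sums, and in both it was A01. The cause was not tested. The limma count of 6909 genes ranged from 5729 to 6893 over 3 settings and from 6149 to 6503 when each recovered library was left out, with no gene against the direction of the deposited table. Of 22 named genes with recovered reads, 9 had a fold that moved by over 1.5 times, or a group at 0, without 1 library, and 0 turned.

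Alternatives set before the data were examined, for pseudocount, low-value filter, scaling between libraries, variance moderation, replicate block, left-out replicates, DESeq2, edgeR, fry and estimated correlation were not run in that form. Over all genes they could not be, since only called genes and group values are given. For the 6930 genes with recovered reads, pseudocount, variance moderation and left-out libraries were varied in limma. DESeq2, edgeR, fry and an estimated correlation were not run on them. No paired analysis was possible because the values carry no replicate numbers. Listed at 0 were 10 genes in doubled haploids, with up to 19.3 in the autotetraploids, and 26 in autotetraploids, with up to 307.4 in the doubled haploids. Whether depth accounts for these was not tested.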

Other observations

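The genes in this and the next paragraph were chosen after their values were seen, except LTI65. No list of iron genes was tested. The iron transporter gene IRT1 (BraA03005220) had 53.1 ± 7.0 normalised reads (SD, n = 3) in autotetraploids against 10.7 ± 3.5 (SD, n = 3) in doubled haploids, and OPT3 (BraA08001047), which acts in the transport of iron in the phloem, had the authors' values of 12691 and 6381. Among the genes for ferritin, the iron storage protein, FER3 had 87.9 ± 11.7 against 374.2 ± 15.7 (SD, n = 3 each) at BraA09002910 and the authors' values of 87.0 and 426.1 at BraA07002249, and ferritin-1 (BraA03000026) had 1240 and 4071. Nicotianamine synthase 3 (BraA06002357) had 7.58 ± 3.77 against 76.5 ± 13.9 (SD, n = 3 each).

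The genes in this paragraph were picked for their high values in the autotetraploids, except LTI65, and the values are the authors'. ATHB-12, a transcription factor of the water deficit response, had 2975 and 102.8 at BraA09002506 and 9306 and 1256 at BraA04000618. The cold and dehydration list, which was fixed in advance, did not pass, with 19 genes higher and 11 lower (Fisher's exact test, adjusted p = 0.349, and from 0.0778 to 0.939 over 8 alternatives), and its member LTI65 (BraA02001678) was lower, with 4314 against 15165. The abscisic acid synthesis gene NCED3 (BraA03003903) had 679.5 and 130.9, while the abscisic acid list that holds it did not pass, with 23 genes higher and 16 lower (Fisher's exact test, adjusted p = 0.553, and from 0.0176 to 0.861 over 8 alternatives). Asparagine synthetase (BraA06000935), a gene induced by carbon starvation, had 2766 and 93.9. The starch-degrading enzyme gene BAM1 (BraA07000828) had 18362 and 3402, and the protease gene CEP1 (BraA03002777), which acts in programmed cell death, had 40762 and 6854. Outside the heat shock list, CLPB1 (BraA07004062), a chaperone, had 1705 and 230.7, and MBF1C (BraA07000807), a regulator of the heat response, had 2162 and 224.5.

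In the patterns below, the tests of expression level, those of chromosome A01 and those that leave out a library were chosen after the result was seen. The other tests were set before their values were seen, although each pattern was found in these data.

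Day-onset clock genes were higher and evening clock genes lower in the autotetraploids. The trend with expression level does not account for it, since within 4 bins of level the split kept p = 2.93e-05 (exact test, two-sided). For the 9 of these genes with recovered reads, the median change of 1.46 (log2, towards the pattern) was still 1.40 or more with any library left out. Their groups overlapped for 0 of 9. The genes were called from these same libraries, so neither value can decide whether 1 library carries the pattern. Genes without recovered reads could not be checked. A candidate explanation, sampling of the groups at different times of day, predicts that other genes of known phase split the same way. Of 10 such genes not matched to the clock list by name, 8 did, or 80%, the lowest share set as support (exact binomial test, p = 0.109). Among the 10, 7 were copies of the catalase genes CAT2 and CAT3. A clock gene listed under another name could also count among the 10. A clock that runs at another phase in autotetraploids predicts the same split, sampling times are not given in the sources used here, and both stay open.

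Ribosomal protein genes were lower in the autotetraploids. Expression level does not account for it, as 15 genes were higher where 230.6 were expected at their level (exact test, p = 5.04e-127). Loss of short transcripts from the autotetraploid libraries predicts that other short proteins fall too. But of 241 called genes in 10 families named for this test, dynein light chains having none, 36.5% were lower (95% interval 30.4% to 42.9%). Under equal sums 56.02% were lower (49.5% to 62.4%). Families ranged from 20% for profilins to 77.8% for LSM and Sm proteins. SAUR genes, without which the auxin list lost its call, supplied 50 of the 241. Of these, 39 were higher, also under equal sums, which lowers both pooled shares. A loss limited to some short transcripts is therefore not excluded. For the 207 genes with recovered reads, the median decrease of 1.19 (log2) was still 1.177 or more with any library left out. Their groups overlapped for 0 of 207. The genes were called from these same libraries, so neither value can decide whether 1 library carries the decrease. The other genes could not be checked. A biological difference between the ploidy groups, or a difference in petal age or time of day, stays open and untested.

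Fewer called genes of chromosome A01 were higher in the autotetraploids. Expression level does not account for it (exact test within bins, p = 8.07e-22). No library deviated on A01 over the 553 A01 genes with recovered reads and a mean of at least 30. The largest difference between libraries of a group was 0.016 on the log2 scale. These genes were called from the same libraries, and A01 genes without recovered reads could not be checked. Loss of 1 of 4 copies of A01 in all autotetraploid plants, with expression in proportion, predicts a shift of -0.42, but the estimate was -0.13 (95% interval -0.22 to -0.08), and with 5 minimum levels from 30 to 3000 it lay between -0.17 and -0.10, with intervals above -0.42 throughout. At the minimum levels of 1000 and 3000 the interval reached 0. A missing copy in some plants, or one with partial compensation, may still give a shift of this size and was not tested.

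Of the 10 splits of the 6 recovered libraries into groups of 3, the real one gave 6909 genes past limma's threshold, and 1 split in all reached that count. The highest of the others gave 0 genes. With 10 splits no share under 0.05 can be reached. The genes had also been called as differing under the real split, so the contrast of 6909 with 0 was largely fixed in advance and decides nothing.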
